A study of Homo sapiens with 6 samples.

How the data were processed

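RNA from MV4;11 cells was measured on 6 Affymetrix whole-transcript arrays, 3 of vehicle-treated cells and 3 of cells treated with an IKK inhibitor at 1 µM. Per the labels' protocols, cells were grown in RPMI medium with serum, total RNA was extracted with the RNeasy Plus Mini kit, and biotin-labelled sense-strand DNA was hybridised. The deposited values are 1 linear probe set intensity (signal) per array for 33252 probe sets, made with Affymetrix Expression Console per the submitters' processing notes. The software version, the summary algorithm and the normalization are not given in the sources used here. The values themselves show a linear scale with a lowest value of exactly 1 on every array and similar medians and quartiles between arrays, so they were taken as already normalized between arrays. Between 27 and 54 of the values of an array were at the lowest signal of 1, fewer on the inhibitor arrays (44, 40 and 27) than on the vehicle arrays (54, 52 and 53). A summary that scales arrays to each other assumes that most genes do not change, so a change shared by all genes cannot be seen in these values.

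Groups and replicate numbers were taken from the sample labels. Probe sets were named with the platform annotation provided, which lists 21214 of them. Of all probe sets, 19460 had exactly 1 gene symbol, 1754 had several and 12038 had none; those with several or none were not named. Symbols were updated through the Entrez gene identifier to the RefSeq gene table of assembly GRCh38.p14, used for names only, in which 19429 of the 19460 were found and 31 kept their annotated symbol. For each of the 18417 genes the probe set with the highest mean over the 6 arrays was used. Among the 769 genes with several probe sets, 2 had probe sets called in opposite directions and 64 had a chosen probe set that was called beside another that was not. No coordinates are given, since no genome build is named for the values. Some genes of the lists below had no single-gene probe set in what was given and are not analysed here. Of the genes to be named in any case these were 4: HOXA7, HOXA9, HOXA10 and BIRC3.

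The log2 of the deposited signal was taken without a pseudocount and without a filter on dim genes. Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. Fold changes are inhibitor over vehicle, errors of log2 fold changes are SE, errors of signals are SD over 3 arrays, and intervals are 95% intervals from the same moderated fit. Gene lists were tested with camera (limma, preset correlation 0.01), which compares the members with all other genes, and adjusted over the 30 lists and 9 families defined by symbol. The lists were targets and components of the NF-kB pathway, HOXA genes with MEIS1, MLL-fusion targets, MYC and p53 targets, DNA replication, mitosis, monocyte, granule, HLA class II, interferon, BCL2 family, FLT3 and STAT5, immediate early, ATF4, ER chaperone, heat shock, NRF2, aryl hydrocarbon receptor, cholesterol, LXR, glycolysis, oxidative phosphorylation, lysosome, chromatin and 4 lists of markers of other lineages. The families were cytosolic and mitochondrial ribosomal proteins, histones, small nucleolar RNAs, microRNA genes, C2H2 zinc fingers, proteasome subunits, olfactory receptors and keratin-associated proteins. A second adjustment was made over the members of each list alone. Alternatives to camera with the preset were fry and camera with the correlation estimated from the data. The latter also tests on only the 4 residual degrees of freedom.

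The design, the lists, the alternatives and the rule for named genes were fixed before the data were examined. Genes named are the 10 largest rises and 10 largest falls among genes past the threshold whose groups do not overlap, leaving out small or uncharacterized RNAs and olfactory receptors; a set of NF-kB targets, pathway members and MLL-fusion targets named whether or not they passed; and up to 4 members of each list with the largest absolute change among those past the threshold, or the 2 of smallest p where none passed. Genes named outside this rule are said to be so.

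Alternatives were quantile normalization of the deposited values, centring each array on its median, leaving out genes under the 40th percentile of mean signal, eBayes with trend and robust options, array weights, the replicate number as a block, the mean of all probe sets of a gene, leaving out each array in turn, an unmoderated test, all probe sets whether named or not, an adjusted p under 0.01, and treat with a minimum fold of 1.2. Taking log2 of the signal plus 16 was added after the values were seen, as were 7 further gene lists, adjusted together with the 39 others. The results were also compared with the 10 splits of the 6 arrays into 3 and 3.

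The steps were tested on simulated data for the comparison of inhibitor with vehicle. Each of 18417 genes had its observed mean over all 6 arrays and its spread as moderated by eBayes. The noise therefore followed the model of the test, and the rates below may differ in real data. A planted log2 change of 0.25 was called in 1.49% of changed genes, one of 0.5 in 62.7% and one of 1 in 93.9%. There were 9 false calls, or 7.89% of all calls. Only 67, 67 and 66 genes were changed at these sizes, against 5341 called in the data. The adjusted threshold was therefore stricter in the simulation, and smaller changes can pass in the data. The NF-kB target genes, lowered by 0.3, were called, and 0 of the 35 lists without their members were. Noise was drawn separately for each gene, so this 0 says nothing about lists of correlated genes. Signal sets the precision: the share of genes called was 8.25% among the lowest 4605 genes by signal, where the median SE was 0.12, and 46.9% among the highest 4604, where it was 0.05. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.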

Results

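Gene expression was measured on whole-transcript Affymetrix arrays in MV4;11, an established human leukemia cell line that carries a fusion of the MLL gene (KMT2A) and an internal tandem duplication of the receptor kinase gene FLT3. The study has 6 arrays, 3 of cells given vehicle and 3 of cells given an inhibitor of IKK at 1 µM. IKK is the kinase complex that activates NF-kB by marking its inhibitor IκB for destruction. The name of the compound and the length of the treatment are not given in the sources used here. The median signal of an array lay between 97.18 and 106.2 and the upper quartile between 412.7 and 429.5, so the arrays were alike in brightness at these points. At the dim end they differed by group. The 1st percentile of log2 signal was 1.986, 2.142 and 1.998 on the vehicle arrays and 2.216, 2.532 and 2.704 on the inhibitor arrays. This bears on rises of very dim genes. Across genes, which are not independent replicates, pairs of vehicle arrays correlated at 0.994 to 0.996 on the log2 scale, pairs of inhibitor arrays at 0.993 and pairs of arrays from different groups at 0.979 to 0.984. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure the spread between these samples, which may be technical, and the number of arrays limits the precision.

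The comparison of inhibitor with vehicle asks which genes change in MV4;11 cells when IKK is inhibited. With the inhibitor, the genes of DNA synthesis and of cell division fell together. Each of the 40 measured genes of DNA replication and the G1/S step was lower, by a median of 2.24-fold, and so was each of the 37 measured genes of G2/M and mitosis, by a median of 2.82-fold. Higher were 15 of 33 lysosomal and autophagy genes, 6 of 10 HLA class II genes and 18 of 39 monocyte and macrophage genes, with 0, 0 and 3 lower. The calls of these 3 lists are lost at an adjusted p = 0.0763, 0.19 and 0.247 with an estimated correlation, and those of both cell cycle lists at an adjusted p = 0.104. Of 45 NF-kB target genes 8 were higher and 5 lower, and the 13 changed are a share near the 29% of all genes. Among the targets of MLL fusions MEIS1, MYB and MYC did not pass the test. Of 18417 genes tested with limma, 5341 (29%) changed at a Benjamini-Hochberg adjusted p under 0.05, 2817 higher and 2524 lower. A change of at least 2-fold was seen for 359 genes, of which 94 were higher and 265 lower, and 60 of those 265 belong to the 77 genes of the 2 cell cycle lists. The 3 values of each group did not overlap for 8081 genes, or 43.9%, where chance gives 10%. Without vehicle replicate 1 the count of changed genes was 3516, and with each array centred on its median it was 1817 higher and 2837 lower, so that 39% of calls were higher in place of 52.7%.

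**Figure D1:**
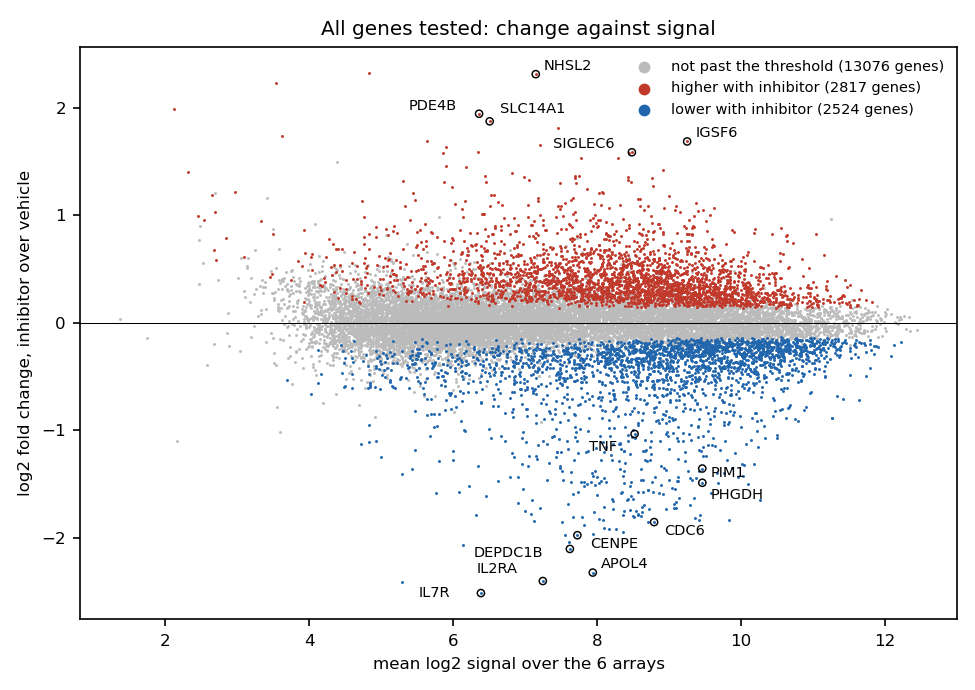
Each point is a gene, with its mean log2 signal over the 6 arrays on the horizontal axis and its log2 fold change, inhibitor over vehicle, on the vertical axis; red points passed the test higher, blue points lower, and grey points did not pass. The 2817 higher genes mostly lie near the zero line, while a group of lower genes of medium to high signal extends below -1, and IL7R at -2.52 is the lowest of the circled genes.

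The 10 named genes with the largest falls include 2 interleukin receptor chains, 3 histone genes and an apolipoprotein L gene. IL7R (probe set 8104901), the alpha chain of the interleukin-7 receptor, fell by 2.52 ± 0.07 (SE) on the log2 scale, from a signal of 200.2 ± 4.09 in vehicle to 35.1 ± 2.93 with inhibitor (SD, n = 3 each, limma adjusted p = 3.93e-05). IL2RA (probe set 7931914), which encodes CD25, the alpha chain of the interleukin-2 receptor, fell from 349 ± 4.38 to 66.0 ± 2.12, a log2 fold change of -2.40. APOL4, of the apolipoprotein L family, had a log2 fold change of -2.33. The log2 fold change was -2.11 for DEPDC1B, -1.98 for the kinetochore motor CENPE, -1.97 for the kinetochore gene SPC25 and -1.95 for the mitotic kinase PBK. The histone genes H2AC14, H2BC3 and H1-1 had log2 fold changes of -2.41, -2.04 and -1.98. Histone genes are near-identical copies of one another, so the level of a single member is uncertain. The probe set of H2AC14 was dim, at 90.8 ± 4.89 in vehicle and 17.5 ± 4.67 with inhibitor.

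Both cell cycle lists fell without exception, with adjusted p = 9.09e-33 for DNA replication and G1/S genes and 3.59e-34 for G2/M and mitosis genes by camera with a preset correlation. With an estimated correlation the adjusted p = 0.104 for each. Adjusted over the list alone, 0 rose and 40 fell in the G1/S list and 0 rose and 37 fell in the G2/M list. CDC6, which loads the replicative helicase onto DNA, fell from 844 ± 30.2 to 234 ± 18.9, a log2 fold change of -1.86. CDC45, GINS2 and E2F8 had log2 fold changes of -1.76, -1.70 and -1.62. Among the mitotic genes, the kinases and motors NEK2 and CENPE and the phosphatase CDC25C had log2 fold changes of -1.92, -1.98 and -1.85, and DLGAP5 of -1.83. Histone genes, defined by symbol and including a few variants that do not follow replication, fell with them, 56 of 66 lower and 1 higher, H2BC12 (log2 fold change 0.64, named after its value was seen). The median log2 fold change of the histones was -0.82 (adjusted p = 1.03e-25 with the preset and adjusted p = 0.0763 with an estimated correlation; adjusted over the list alone, 2 rose and 57 fell).

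The largest rises were found in genes of varied function. NHSL2 (probe set 8168359) rose from 63.7 ± 0.818 to 316 ± 16.2, a log2 fold change of 2.31 ± 0.05 (SE, adjusted p = 3.93e-05). PDE4B, a phosphodiesterase that breaks down cyclic AMP, rose from 42.0 ± 3.86 to 161 ± 10.3, and SLC14A1, a urea transporter, from 47.6 ± 1.72 to 174 ± 5.88. CRLF2, a receptor subunit for the cytokine TSLP, rose from 27.8 ± 3.04 to 90.2 ± 13.0. DNASE2, the DNase of lysosomes, had a log2 fold change of 1.65, and CSGALNACT1, an enzyme of chondroitin sulfate synthesis, of 1.59. The surface proteins IGSF6 and SIGLEC6 had log2 fold changes of 1.69 and 1.58. The cytochrome P450 gene CYP2B6 and its pseudogene CYP2B7P had log2 fold changes of 1.63 and 1.81, and since their sequences are nearly the same the array may not separate them.

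NF-kB target genes showed no common direction. Of 45 measured members 8 rose, 5 fell and 32 did not pass, with the same counts adjusted over the list alone, and the median log2 fold change was 0.02 (camera adjusted p = 0.642). The 13 that changed are a share near the 29% of all genes. TNF (probe set 8118142), which encodes tumor necrosis factor, fell from 527 ± 46.7 to 257 ± 18.0, a log2 fold change of -1.04 ± 0.09 (SE, adjusted p = 0.000503). The anti-apoptotic gene BCL2A1 and the chemokine gene CCL2 fell with log2 fold changes of -0.39 and -0.63, the call for CCL2 being lost without vehicle replicate 1, 2 or 3 or inhibitor replicate 2 (adjusted p = 0.0899, 0.0886, 0.101 and 0.0617). NFKB2 and BCL3, themselves members of the NF-kB and IκB families, rose with log2 fold changes of 0.63 and 0.58, and so did NFKBIA, which encodes IκBα, at 0.37. The values of NFKB1 (log2 fold change 0.05), RELB (-0.03), TNFAIP3 (0.05), CXCL8 (0.29), CCL3 (-0.02) and ICAM1 (0.14) did not pass. IL1B had a log2 fold change of -0.37 (adjusted p = 0.0732), which passed without inhibitor replicate 2 (adjusted p = 0.0219). With each array centred on its median, 4 members rose and 6 fell, and the median was -0.04; after quantile normalization 8 rose and 6 fell, and the median lay just under zero.

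Among the components of the NF-kB pathway, 5 of 23 rose and 2 fell (adjusted p = 0.666; adjusted over the list alone, 5 rose and 3 fell). CHUK, which encodes the kinase IKKα, fell from 530.4 ± 18.8 to 399 ± 9.52, a log2 fold change of -0.41. MAP3K14, which encodes the kinase NIK of the alternative pathway, rose with a log2 fold change of 0.39. IKBKB, IKBKG and RELA, with log2 fold changes of 0.10, -0.18 and -0.01, did not pass. Under median centring 1 member of this list rose and 2 fell. Without vehicle replicate 1, 2 or 3 or inhibitor replicate 3 the number that rose was 2 in each case, and without inhibitor replicate 2 it was 3. The number that fell was 1 without vehicle replicate 1.

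Targets of MLL fusion proteins were slightly higher as a list. Of 29 measured members 8 rose, 2 fell and 19 did not pass, with the same counts adjusted over the list alone, and the median log2 fold change was 0.09 (camera adjusted p = 0.0225). That call is lost with an adjusted p = 0.305 with an estimated correlation, 0.148 after median centring, 0.0971 without vehicle replicate 3 and 0.0525 without inhibitor replicate 1; over the other arrays left out in turn and the remaining settings the adjusted p was 0.00062 to 0.0491. Of its members 5 rose and 3 fell with median centring, 10 and 3 after quantile normalization, and 5 rose without vehicle replicate 1. JMJD1C, a histone demethylase family member, rose from 1223 ± 28.7 to 1685 ± 27.8 (log2 fold change 0.46, adjusted p = 0.000744). TAPT1, FLT3 and CPEB2 rose with log2 fold changes of 0.40, 0.32 and 0.31. BCL2, the anti-apoptotic gene, had a log2 fold change of 0.17 (adjusted p = 0.0263), lost without vehicle replicate 1, 2 or 3 (0.093, 0.0762 and 0.0677) and without inhibitor replicate 2 or 3 (0.0778 and 0.0644). The 2 members that fell, named after their values were seen, were the elongation factor gene ELL2 (-0.23) and DOT1L (-0.19), which encodes a histone methyltransferase recruited by MLL fusions. Of the members, 1 fell when any array but inhibitor replicate 2 was left out. MEIS1 (log2 fold change 0.09, 95% interval -0.01 to 0.19), PBX3 (0.04), MEF2C (0.01), CDK6 (0.11), MYB (0.03) and MYC (0.07) did not pass. In the list of HOXA genes with MEIS1 and its partners, 3 of 14 genes were measured, HOXA2, MEIS1 and PBX3, and none passed (camera adjusted p = 0.576), with the same 0 adjusted over the list alone and 0 at an unadjusted p under 0.05 by limma. HOXA7, HOXA9 and HOXA10 were not measured, and the signal of HOXA2 was low, 37.85 in vehicle and 39.42 with inhibitor. By fry this list passed (adjusted p = 0.0292), and by camera it passed under no setting.

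**Figure D2:**
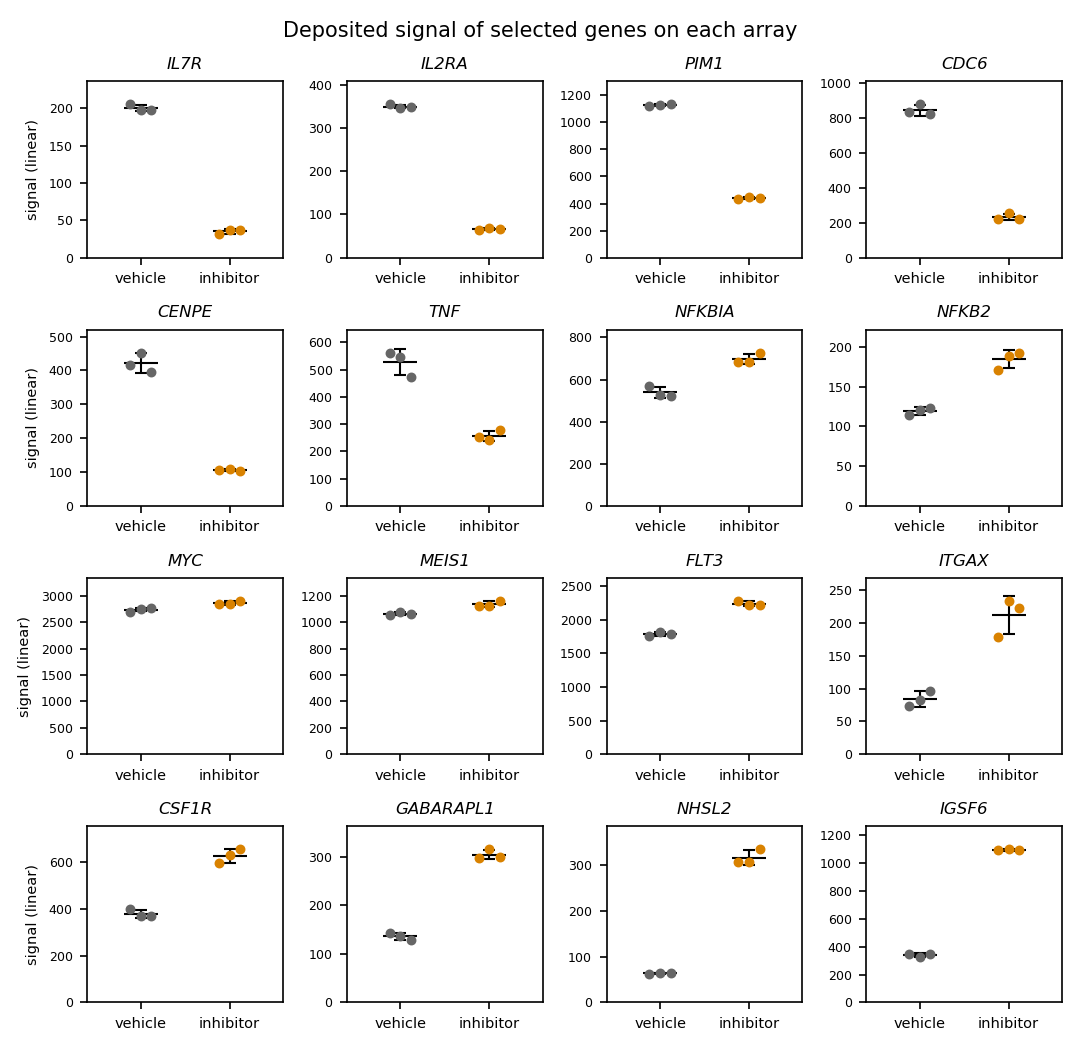
Each panel gives the deposited linear signal of a gene on the 3 vehicle and the 3 inhibitor arrays, with the mean as a horizontal bar and the SD as error bars; axes start at zero. IL2RA fell from 349 to 66.0 and TNF from 527 to 257, NFKB2 rose from 119 to 184, and MYC at 2742 and 2872 and MEIS1 at 1066 and 1137 did not pass.

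Response genes of FLT3 and STAT5, which lie downstream of the mutated receptor, included some of the deepest falls. Of 27 measured genes 3 rose and 9 fell (adjusted over the list alone, 3 rose and 12 fell). Besides IL2RA, the phosphatase gene CDC25A fell from 438 ± 4.59 to 155 ± 4.51, the kinase gene PIM1 from 1128 ± 4.74 to 440.5 ± 9.97, and the immediate early gene EGR1 had a log2 fold change of -0.67. The 3 that rose were BCL6, STAT5A and STAT5B (log2 fold changes 0.65, 0.58 and 0.16, named after their values were seen). The median was -0.06 and the mean -0.24, and the camera adjusted p = 0.0376 became an adjusted p = 0.232 with an estimated correlation. The call for FLT3 and STAT5 response genes was also lost without inhibitor replicate 1 (0.0668), inhibitor replicate 2 (0.0672) or vehicle replicate 2 (0.0552), after quantile normalization (0.107) and without dim genes (0.0699). Without vehicle replicate 1 the number that fell was 5.

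Several lists tied to protein production and turnover had more members lower than higher, while of the cytosolic ribosomal protein genes 17 of 67 rose and 3 fell, or 4 and 4 with median centring, and 7 rose without vehicle replicate 1. MYC target genes had 24 of 38 members lower and 0 higher, with a median log2 fold change of -0.24 (adjusted p = 2.6e-10, or adjusted p = 0.0763 with an estimated correlation; adjusted over the list alone, 25 fell). Among them were the ribosome assembly gene MRTO4 (-0.74) and the mitochondrial chaperonin gene HSPE1 (-0.71), while MYC itself did not pass. Proteasome genes, defined by symbol, had 29 of 37 lower and 0 higher, with PSMC3 at -0.72 and PSMD14 at -0.53, and a median of -0.30 (adjusted p = 9.94e-12, or adjusted p = 0.0776 with an estimated correlation; adjusted over the list alone, 32 fell). The symbol also takes in PSMC3IP (-0.65), a recombination gene that is no proteasome subunit. Mitochondrial ribosomal protein genes had 44 of 74 lower and 1 higher, with MRPL13 at -0.76 and MRPL28 at -0.56 (adjusted p = 2.15e-11, or adjusted p = 0.0763 with an estimated correlation; adjusted over the list alone, 3 rose and 51 fell), and 29 fell without vehicle replicate 1. Of the heat shock genes 16 of 23 fell and 1 rose, with HSPA4L at -0.67 and HSPH1 at -0.61 (adjusted p = 8.21e-07, or adjusted p = 0.104 with an estimated correlation; adjusted over the list alone, 1 rose and 18 fell). Among ER chaperones and XBP1 targets 13 of 28 fell and 2 rose, with DERL3 at -0.75 and the disulfide isomerase gene PDIA4 at -0.64 (adjusted p = 0.000157, or adjusted p = 0.104 with an estimated correlation; adjusted over the list alone, 3 rose and 15 fell). Of these, 0 rose with median centring or without vehicle replicate 1 or 3 or inhibitor replicate 1 or 3, and 1 rose without vehicle replicate 2 or inhibitor replicate 2. The 1 heat shock riser was lost without vehicle replicate 1, and the 1 mitochondrial ribosomal riser when any array but inhibitor replicate 1 was left out.

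In cholesterol synthesis and its SREBP-driven neighbours 16 of 27 genes fell and 0 rose, among them DHCR7, the last enzyme of the pathway, from 404 ± 18.5 to 204 ± 16.3, the fatty acid desaturase gene FADS2 (log2 fold change -0.96) and SCD (-0.83). The median was -0.28 (adjusted p = 4.28e-07, or adjusted p = 0.104 with an estimated correlation; adjusted over the list alone, 17 fell). Of the ATF4 and amino acid response genes 18 of 43 fell and 4 rose (adjusted p = 0.000238, or adjusted p = 0.275 with an estimated correlation; adjusted over the list alone, 6 rose and 18 fell). PHGDH and PSAT1, which catalyse the opening steps of serine synthesis, fell with log2 fold changes of -1.49 and -0.70, whereas the lipoprotein receptor gene VLDLR rose by 0.70. Oxidative phosphorylation subunits had 22 of 46 genes lower and 2 higher, with NDUFAB1 at -0.53 and NDUFA9 at -0.47 (adjusted p = 1.34e-05, or adjusted p = 0.0763 with an estimated correlation; the same counts adjusted over the list alone), and without vehicle replicate 1 or inhibitor replicate 3 the number of these subunits that fell was 14 in each case. Of the subunits 0 rose with median centring and 1 after quantile normalization, and 1 rose when any array but vehicle replicate 2 was left out. Among p53 target genes 11 of 30 fell and 4 rose, with PLK2 at -0.73, SPATA18 at -0.67 and DDB2 at -0.66 against ZMAT3 at 0.65, and 2 rose with median centring (adjusted p = 0.00846, or adjusted p = 0.104 with an estimated correlation; the same counts adjusted over the list alone).

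Lysosomal and autophagy genes rose, 15 of 33 higher and 0 lower, with a median log2 fold change of 0.19 (adjusted p = 2.94e-06, or adjusted p = 0.0763 with an estimated correlation; adjusted over the list alone, 19 rose and 0 fell). GABARAPL1, a member of the ATG8 family of autophagosome proteins, rose from 136 ± 6.80 to 305 ± 9.65, and the lysosomal lipid and glycan genes NPC2, PSAP and NEU1 had log2 fold changes of 0.84, 0.83 and 0.81. Monocyte and macrophage genes had 18 of 39 members higher and 3 lower, with a median of 0.23 (adjusted p = 0.00066, or adjusted p = 0.247 with an estimated correlation; the same counts adjusted over the list alone). The integrin gene ITGAX (CD11c) rose from 84.4 ± 11.6 to 212 ± 29.2, the protease gene CTSS from 479 ± 23.4 to 845 ± 10.7, and CSF1R, the receptor for macrophage colony-stimulating factor, from 380 ± 16.6 to 626 ± 30.4. Against this direction, S100A8, a calcium-binding protein gene of monocytes and neutrophils, fell from 197 ± 7.24 to 72.6 ± 3.68, and AIF1 and CD1D passed lower (-0.15 and -0.41, named after their values were seen). The number of monocyte genes that fell was 1 without vehicle replicate 1 or 3 or inhibitor replicate 1 or 3. HLA class II genes had 6 of 10 higher and 0 lower, the same counts adjusted over the list alone, with HLA-DQB1 at 1.45, HLA-DMA at 1.04 and HLA-DPA1 at 0.99 (adjusted p = 0.00447, or adjusted p = 0.19 with an estimated correlation). These genes are polymorphic and share sequence, so values of single members are uncertain.

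Interferon-stimulated genes had 11 of 41 higher and 0 lower, led by IFITM3, RSAD2 and IFIH1 with log2 fold changes of 0.84, 0.83 and 0.73 (adjusted p = 0.0159, or adjusted p = 0.176 with an estimated correlation; adjusted over the list alone, 10 rose and 0 fell). With median centring 8 rose and 2 fell, after quantile normalization 13 and 2, and the number that fell was 1 without vehicle replicate 1 or inhibitor replicate 2 and 2 without inhibitor replicate 1. NRF2 target genes had 10 of 27 higher and 3 lower (adjusted p = 0.0109, or adjusted p = 0.176 with an estimated correlation; adjusted over the list alone, 11 rose and 3 fell). EPHX1, an epoxide hydrolase gene, rose from 447 ± 11.3 to 868 ± 14.6 and the heme transporter gene SLC48A1 from a mean signal of 480 to 889, while AKR1C1, whose sequence is close to that of other AKR1C genes, fell with a log2 fold change of -1.79. A second probe set of AKR1C1, of similar signal, had a log2 fold change of -0.73, so the size of this fall is uncertain.

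**Figure D3:**
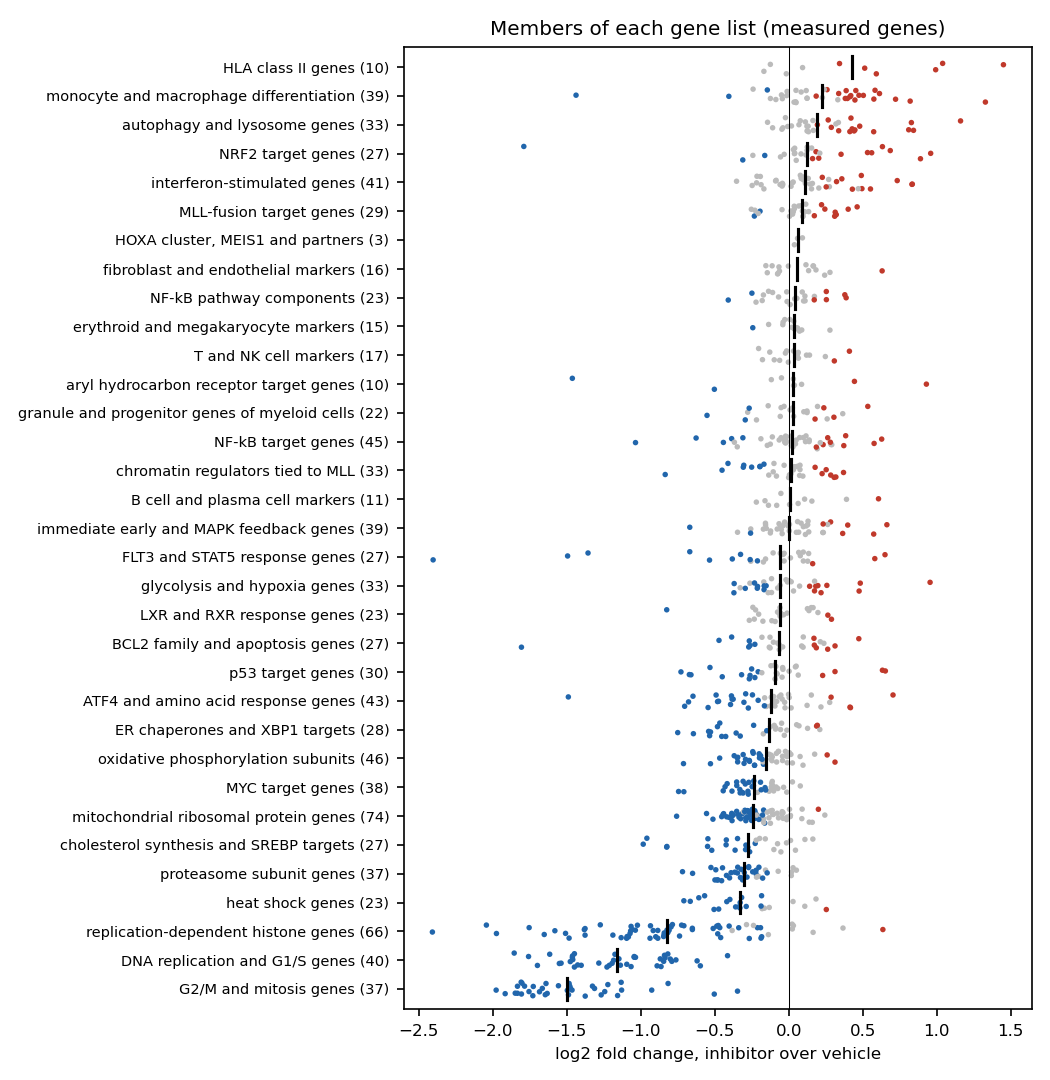
Points are the measured members of 33 gene lists and symbol families, placed by log2 fold change, inhibitor over vehicle (red, passed higher; blue, passed lower; grey, did not pass), with the median as a black bar and the number of measured members in brackets; the vertical scatter has no meaning. The medians of G2/M and DNA replication genes lie at -1.50 and -1.16, that of HLA class II genes at 0.43, and that of NF-kB target genes at 0.02.

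Families of small RNAs and of repeated genes moved by less certain amounts. Small nucleolar RNA genes had 68 of 192 higher and 7 lower, with a median log2 fold change of 0.28 (adjusted p = 2.04e-06, or adjusted p = 0.361 with an estimated correlation; adjusted over the list alone, 75 rose and 10 fell). Without vehicle replicate 1 the number that rose was 42, and without inhibitor replicate 2 the number that fell was 11, against 12 after quantile normalization. The largest changes in this family, of SNORD115-32 from a mean signal of 13.0 to 64.7 and SNORD115-40 from 5.40 ± 0.69 to 25.6 ± 5.74, were near the lowest signals of the arrays and belong to a cluster of near-identical copies. Precursor and host genes of microRNAs had 22 of 189 higher and 5 lower, among them MIR223, a microRNA of myeloid cells, from a mean signal of 452 to 977, and MIR21 from 61.1 ± 0.387 to 141 ± 27.2. The call for microRNA host and precursor genes (adjusted p = 0.0371) became an adjusted p = 0.648 with an estimated correlation and was also lost without inhibitor replicate 2 (0.0572) or vehicle replicate 2 (0.0896), after quantile normalization (0.304), without dim genes (0.163) and by fry (0.111); adjusted over the list alone, 14 rose and 2 fell. After quantile normalization 15 microRNA genes rose and 8 fell, and with median centring 21 and 8. The number of microRNA genes that fell was 1 without vehicle replicate 1 or 3, 3 without inhibitor replicate 2 and 2 without inhibitor replicate 3. Zinc finger genes of the C2H2 type had 155 of 494 higher and 25 lower, with ZNF283 at 1.14 and ZNF367 at -1.39 (adjusted p = 3.74e-06, or adjusted p = 0.0763 with an estimated correlation; adjusted over the list alone, 167 rose and 31 fell). Cytosolic ribosomal protein genes had 17 of 67 higher and 3 lower, with RPL22 at 0.50 and the paralogs RPL39L and RPS27L at -1.21 and -0.50 (adjusted p = 0.000166, or adjusted p = 0.0763 with an estimated correlation; adjusted over the list alone, 18 rose and 3 fell). With median centring 4 of the ribosomal protein genes rose and 4 fell, and the median log2 fold change was 0.04 for ribosomal protein genes. Without vehicle replicate 1 or 2 or inhibitor replicate 3 the number that rose was 7, 10 and 11.

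The remaining lists did not pass camera. Granule and progenitor genes of myeloid cells had 4 of 22 higher and 3 lower (adjusted p = 0.642; adjusted over the list alone, 6 rose and 3 fell), with the myeloperoxidase gene MPO at -0.55 and MSI2 at 0.53. BCL2 family and apoptosis genes had 6 of 27 higher and 7 lower (adjusted p = 0.481, or 0.00216 by fry; adjusted over the list alone, 8 rose and 9 fell), with BIRC5, also a mitotic gene, at -1.81 (less on a dimmer second probe set, -0.996) and CASP9 at 0.47. Immediate early and MAPK feedback genes had 6 of 39 higher and 2 lower (adjusted p = 0.642; adjusted over the list alone, 6 rose and 1 fell), with KLF10 at 0.66 and DUSP10 at 0.57. Chromatin regulators tied to MLL had 7 of 33 higher and 9 lower, the same counts adjusted over the list alone (adjusted p = 0.666), with the methyltransferase gene EZH2 from 1282 ± 41.9 to 719 ± 49.6, WDR5 at -0.45 and AFF4 at 0.37. Glycolysis and hypoxia genes had 9 of 33 higher and 9 lower (adjusted p = 0.642; adjusted over the list alone, 9 rose and 10 fell), with ALDOC at 0.96 and NDRG1 and KDM3A at 0.48 each. Among aryl hydrocarbon receptor targets 2 of 10 rose and 2 fell, the same counts adjusted over the list alone (adjusted p = 0.996), with CYP1B1 at -1.46 and LRRC25 at 0.93. LXR and RXR response genes had 2 of 23 higher and 1, SCD, lower, the same counts adjusted over the list alone (adjusted p = 0.642). The balance of several of these lists depends on scaling. With median centring the glycolysis and hypoxia genes had 3 higher and 10 lower, the chromatin regulators 3 and 10, the BCL2 family 2 and 8, the immediate early genes 3 and 4, the granule genes 2 and 3 and the LXR and RXR response genes 1 and 2. After quantile normalization the glycolysis and hypoxia genes had 8 higher and 5 lower, and the LXR and RXR response genes 3 and 2. Leaving out 1 array also moved several of these counts: whichever array was left out, the glycolysis and hypoxia genes had 2 to 5 lower and the BCL2 family 2 to 3 higher, and the glycolysis genes had 4 higher without vehicle replicate 1 and 5 without vehicle replicate 2. Chromatin regulators had 5 lower without vehicle replicate 1, 2 or 3 or inhibitor replicate 3, and 4 higher without vehicle replicate 1. Granule genes had 2 higher without vehicle replicate 2 or 3 or inhibitor replicate 2, and immediate early genes 3 higher without vehicle replicate 2. The immediate early genes had 1 lower when any array but vehicle replicate 3 was left out, and the aryl hydrocarbon receptor targets 1 lower when any array but inhibitor replicate 1 was left out. LXR and RXR response genes had 0 higher without inhibitor replicate 3, 1 higher without vehicle replicate 1 or 2 or inhibitor replicate 2, and 2 lower without vehicle replicate 3 or inhibitor replicate 1 or 2.

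Markers of other cell types and families seldom expressed in blood cells did not pass either. T and NK cell markers had 2 of 17 higher, NKG7 (log2 fold change 0.41, at a vehicle signal of 1236) and CD3G (0.31, lost without vehicle replicate 2 or 3 or inhibitor replicate 1 at adjusted p = 0.0685, 0.0613 and 0.0545), and 0 lower (adjusted p = 0.739). B cell and plasma cell markers had 1 of 11 higher, the dim JCHAIN, and 0 lower (adjusted p = 0.903). Of 16 fibroblast and endothelial markers 1 rose, PECAM1, which myeloid cells also express, from 874 ± 17.9 to 1353 ± 19.0 (adjusted p = 0.697 for the list). Counts in these 3 lists were the same adjusted over the list alone. Erythroid and megakaryocyte markers had 0 of 15 higher and 1 lower, EPOR at -0.24, which was not called adjusted over the list alone or without vehicle replicate 2 or 3 or inhibitor replicate 1 or 2 (0.0636, 0.063, 0.0641 and 0.0807; adjusted p = 0.996 for the list). Olfactory receptor genes had 12 of 341 higher and 7 lower (adjusted p = 0.739), and keratin-associated protein genes 2 of 68 higher and 2 lower (adjusted p = 0.744); adjusted over the list alone, 0 rose and 0 fell in both families. For the olfactory receptor genes the balance turned with scaling, to 7 higher and 12 lower after quantile normalization and 6 and 13 with median centring, and the keratin-associated protein genes had 1 and 2, and 1 and 3. Of the olfactory receptor genes 3 fell without vehicle replicate 2, 13 without inhibitor replicate 1 and 4 without inhibitor replicate 3. Of the keratin-associated protein genes 0 rose and 0 fell without vehicle replicate 1, 1 rose without vehicle replicate 2 or inhibitor replicate 1 or 3, and 1 fell without inhibitor replicate 1. Without inhibitor replicate 1, 1 of the T and NK cell markers fell. In addition, 2 B cell markers rose without vehicle replicate 2, and 2 fibroblast and endothelial markers without vehicle replicate 3 or inhibitor replicate 1.

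Over all 39 lists and families, 23 passed camera with its preset correlation, 13 lower and 10 higher. With an estimated correlation 0 passed, the lowest adjusted p being 0.076, and 14 had an unadjusted p under 0.05, while fry, which tests a list without setting it against other genes, called 24. The estimated setting tests on 4 residual degrees of freedom, so a call can be lost there without a high correlation. For lysosomal and autophagy genes the estimated correlation was -0.0081, under the preset 0.01, yet the camera p went from 7.54e-07 to 0.00473. It was 0.42 and 0.49 for the G1/S and G2/M lists. Splits of the same arrays that mix the groups gave 9 to 15 lists past the preset threshold. Each mixed split sets unequal numbers of inhibitor arrays against each other, so part of the treatment difference stays in it. For G2/M and mitosis genes a mixed split gave a median log2 fold change as large as 0.584 in size, against 1.5 in the real one. These counts, and the p-values that follow, therefore do not measure chance. At least 1 mixed split gave a smaller camera p than the real one for monocyte genes (3.54e-06 against 0.000271), HLA class II genes (0.00172 against 0.00195), ribosomal protein genes (5e-06 against 5.95e-05) and C2H2 zinc finger genes (1.38e-08 against 1.06e-06). The same holds for MLL-fusion, p53 and NRF2 targets, FLT3 and STAT5 response genes, small nucleolar RNAs and microRNA genes.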

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

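Both results here concern probe sets outside the comparison of named genes and were looked at only after the fit over all probe sets; no explanation was tested for either. In a fit over all 33252 probe sets, 6172 passed the threshold. Of these, 1248 are absent from the annotation and so have no gene symbol, 865 higher and 383 lower with the inhibitor. Only those with a mean log2 signal at or above the median of all values were looked at singly. The largest fall among them was that of probe set 7924069, with a log2 fold change of -3.73 ± 0.23 (SE, limma adjusted p = 0.000648). Its signals were 366 to 557 on the vehicle arrays against 27.1 to 43.3 on the inhibitor arrays, a larger fall than that of any named gene. Probe set 8156194 had a log2 fold change of -1.98, and probe sets 7937798 and 8021635 of 2.17 and 2.02.

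On inhibitor replicate 3 alone, the unnamed probe set 7893266 had a signal of 21913, the highest value of the 6 arrays, against 1452 to 1842 on the other 5 arrays. The next highest maximum of an array was 9359, on inhibitor replicate 2.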

How the results depend on the processing

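The setting with log2 of the signal plus 16 was chosen only after the values were seen. No gene was called in opposite directions under any setting with calls per gene that was compared (0 each), but the balance of calls turned: quantile normalization gave 2644 higher and 2786 lower genes and centring 1817 and 2837. The median of NF-kB target genes, 0.02, turned negative under both, at -0.001864 and -0.03572, and without vehicle replicate 2 or inhibitor replicate 1, with no call in any of these. Changed genes numbered 3048 (1550 higher, 1498 lower) at an adjusted p under 0.01, a stricter threshold on the same test. Centring moved the median of all genes from 0.01 to -0.04; 4244 of the 5341 calls were shared. The labels do not say that replicate numbers pair the cultures, and deviations of same-numbered arrays correlated at -0.03, -0.15 and -0.10, so the block has no basis in the design: with it there were 3249 calls (1726 higher, 1523 lower), no list changed its call, and 0 MLL-fusion targets fell. Leaving out each array in turn gave 3516 to 4922 changed genes, 1836 to 2530 higher and 1680 to 2392 lower. For changes of at least 2-fold, leaving out dim genes gave 58 higher among the genes kept, and treat, which tests for a smaller fold, gave 1385 (663 higher, 722 lower). With an estimated correlation 0 lists passed. The median of MLL-fusion targets was 0.03757 after centring, 0.09228 with the estimated correlation, and 0.0721 to 0.08621 without each array in turn; the cause was not tested. Of the 171 named genes, 7 calls were lost with centring, 4 with quantile normalization and 9 to 17 without an array. Signal limits what can be called, as the share of called genes by signal shows.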

Other observations

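The 7 gene lists in this paragraph and the next were chosen only after the results were seen. So were the tests of low signal among NF-kB targets, of array scaling and of cells of other lineages. Of 30 target genes of the FOXO transcription factors, 17 were higher and 1, GADD45A, lower (log2 fold change -0.32). The other 12, among them CAT and SOD2 (0.06 and 0.03), did not pass. The median log2 fold change was 0.26 (camera adjusted p = 1.97e-06, adjusted p = 0.0737 with an estimated correlation, both over all 46 lists). DEPTOR, an inhibitor of mTOR, and ARRDC3 had log2 fold changes of 1.42 and 1.35, and the insulin receptor gene INSR of 0.76; 10 of the 30 genes are also in lists described above. In a list of lysosomal enzymes and cofactors, most of them of glycan and sphingolipid breakdown, 16 of 30 rose and 1, ARSB, fell (adjusted p = 4.62e-06, adjusted p = 0.0696 with an estimated correlation), with IDUA, SGSH and MANBA at 1.34, 1.30 and 1.24. The risers include DNASE2 and PLD3, which are nucleases, the peptidase gene TPP1, and HGSNAT and SUMF1, which are not hydrolases. The toll-like receptor genes TLR6, TLR1 and TLR2 had log2 fold changes of 0.91, 0.91 and 0.61, in a list with 4 of 12 higher and 1 lower and 3 genes shared with lists described above (adjusted p = 0.0392, adjusted p = 0.177 with an estimated correlation).

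Genes of the Fanconi anemia pathway and homologous recombination had 21 of 24 lower and 1, FANCF, higher, with a median log2 fold change of -1.10 (adjusted p = 1.33e-15, adjusted p = 0.0916 with an estimated correlation). BRCA1, XRCC2 and EXO1 had log2 fold changes of -1.36, -1.57 and -1.64. Kinetochore and centromere genes had 27 of 29 lower and 0 higher, NUF2 among them at -1.92, with a median of -1.19 (adjusted p = 2.53e-22, adjusted p = 0.0696 with an estimated correlation); neither shares a gene with the lists described above. Cytosolic aminoacyl-tRNA synthetases had 13 of 19 lower and 1, QARS1, higher (adjusted p = 8.37e-06, adjusted p = 0.12 with an estimated correlation), and 10 of the 19 are also in lists described above. Among receptors that share the common gamma chain, or resemble those that do, 2 of 9 rose, CRLF2 and IL4R, 2 fell, IL7R and IL2RA, and 5 did not pass (adjusted p = 0.523). With an estimated correlation 0 of the 46 lists passed; adjusted only among themselves the FOXO, lysosomal enzyme, Fanconi and kinetochore lists had 0.0348 to 0.0437, but they were chosen from changes already seen.

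With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. Every split but the real one has both treatments in each group. The treatment difference then adds to the spread within groups, which lowers gene calls, and part of it stays between the groups. The mixed splits are therefore no measure of what chance gives. In 1 of the 10 splits, the real one, the count of changed genes was as large as 5341, and the highest of the other splits was 0; for changes of at least 2-fold the split count was also 1, with 359 against 0. For lists past the threshold it was 1, with 23 in the real split and 15 as the highest other. For NF-kB target genes 3 of the 10 splits gave as small a camera p (-log10 p of 0.33 in the real split, highest other 0.65), and for MLL-fusion target genes 2 did (1.92 and 2.77).

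The absence of a common direction among NF-kB target genes is a pattern to follow up under an inhibitor of IKK. That imprecise signals hide a fall of 1.5-fold in most members is argued against by 38 of 45, or 84.4%, whose 95% interval excludes it. A smaller common fall is not excluded by this, and that of MYC target genes, for example, was 1.18-fold at the median. Whether low signal hides a fall stays open. The 38 were not split by signal, and a dim member may exclude a fall because it has little room to drop. Among the 22 members at or above the median signal of all genes 7 rose and 3 fell, and the exact two-sided sign test gave p = 0.344. A biological explanation, that basal expression of most of these genes in MV4;11 may rest little on IKK at the time sampled, was not tested, and neither was whether the compound inhibited IKK in these arrays.

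The fall of DNA replication and mitosis genes had a median log2 fold change of -1.38 over 77 genes. The median was -1.37 after quantile normalization. The arrays were already alike in brightness, with gene medians of 7.323 to 7.457 on the log2 scale, so that setting could move it little. Differences in brightness that small could not give the whole fall. Cells of 4 other lineages, if they expressed none of these genes, would have to make up 61.5% of the treated cultures to dilute them so far. The lowest share of markers in the 4 lists whose interval excludes a 2-fold rise was 93.8%, and 58 of all 59 markers excluded it. This argues against cells of these 4 lineages making up most of the treated cultures. In all, 4 of 59 markers rose (6.78%, against 15.3% of all genes, exact binomial p = 0.071). That count of rises cannot decide the question by itself, since only 11 of the 59 were at or above the median signal and dim genes are called less often. Rises were called for 222 of the lowest 4605 genes by signal and for 498 of the next 4604. The binomial test also takes the markers as independent. Slower division of the treated cells may be a cause, as a hypothesis that was not tested, since division was not measured; cell counts or DNA content of the same cultures would test it.

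Of 192 small nucleolar RNA genes 68 rose, 7 fell and 117 did not pass, with a median log2 fold change of 0.28. The camera call of the family (adjusted p = 2.04e-06) was lost with an estimated correlation (adjusted p = 0.361). Dim probe sets as the cause are argued against by the 76 genes of the family at or above the median signal, whose median was 0.37 (bootstrap 95% interval 0.25 to 0.42; 40 rose and 5 fell), and a single array with more small RNA by the lowest median without any array, 0.24. A difference in RNA recovery between the groups stays open, as it could raise short RNAs on every array of a group. Mixed splits of the arrays set this family apart too, as they do other lists, with 3 of 10 camera p-values as small as the real 4.7e-07, the lowest other being 1.98e-18, although the largest median of another split was below the real one in size. Mixed splits keep part of any treatment difference, so they do not measure chance. No biological explanation was tested.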
